A study of Rattus norvegicus with 13 samples.

How the data were processed

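RNA of the left ventricle of male rats aged 45 weeks was measured on 13 Agilent arrays with a single dye, Cy3, of which 6 held wild-type (WT) tissue and 7 held tissue of rats overexpressing the β3-adrenergic receptor (Adrb3). The series' own description counts 4 WT and 5 overexpressing rats. Per the labels, hearts 1 and 2 of each group are replicate labelings of the RNA of 1 rat. WT heart 5 and overexpressing heart 4 are replicate hybridizations, and the labels do not name the array they repeat. Rats are called here by group and heart number: WT 1, 3, 4 and 6, and overexpressing 1, 3, 5, 6 and 7. How the receptor was overexpressed, and which sequence was introduced, is not given in the sources used here.

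The scanner files deposited by the authors hold the brightness (intensity) of each spot, made with Agilent Feature Extraction 10.7.1.1 on array design 028279, per the file headers. The processed signal in them is a background-subtracted and spatially detrended intensity, per the file headers, and no scaling between arrays is recorded there. The deposited series table holds natural log values with no stated scale. Set against the scanner values of the same array, the authors' natural log values follow the natural log of the median spot signal with slopes of 0.986 to 1.063 and correlations across probes of 0.9988 to 0.9999. The direction and log base of that table were taken from this match, while its scaling between arrays is not given in the sources used here. Its column medians lay between 5.695 and 5.73, and it covers 20000 of the 30367 probes, of which 94.7% were well above background on at least 1 array against 30.7% of those outside it. It served as an alternative only.

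From the scanner files, log2 of the processed signal minus the 75th percentile of the same array was computed for the 58717 spots that are not controls. Spots of a probe were averaged on the log2 scale, leaving out spots that the software marked as outliers where another spot of the probe remained. A probe counted as well above background on an array when at least 0.5 of its spots were, and as well above it in a rat when this held on all arrays of that rat. The labelings of 1 rat were averaged, and the replicate hybridizations were left out of the main comparison because their partner is not named, which leaves 4 WT and 5 overexpressing rats with 1 value each. A probe was kept when well above background in at least 4 of the 9 rats, which 17587 probes were. Each gene name was represented by its probe with the highest mean, giving 15367 genes. Of these, 11179 carry a gene symbol and 4188 another kind of name. Names in the files are those of the array design. Through the RefSeq gene table of assembly GRCr8, 11561 of the tested genes were matched to a present symbol, 9922 of them by accession. The file headers name build rn4 for the array design, so no coordinates are printed and the table was used only for names and gene order.

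Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the single term and Benjamini-Hochberg adjustment over all genes at 0.05. Single values were compared with an exact two-sided permutation test over the 126 splits of 9 rats into 4 and 5. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 30 lists, beside camera with an estimated correlation and fry. Values of a list are means of its members' log2 values per rat. The tests, the gene lists and most alternatives were fixed before the data were examined. Tables were read with the R package data.table, version 1.17.8, and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and the plots were drawn with matplotlib 3.10.9.

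The lists were adrenergic receptors and cAMP signalling, nitric oxide and cGMP signalling, cardiac stress and hypertrophy markers, extracellular matrix and fibrosis, calcium handling, sarcomere and cardiomyocyte structure, fatty acid oxidation and lipid handling, glucose metabolism, mitochondrial respiratory chain and ATP synthase, redox and antioxidant genes, inflammatory cytokines and chemokines, interferon response, MHC genes, angiogenesis and endothelial activation, immediate early genes, heat shock and chaperones, circadian clock, ion channels of the cardiac action potential, cell cycle, and renin-angiotensin and corticosteroid signalling. Markers of endothelial cells, fibroblasts, smooth muscle and pericytes, macrophages and myeloid cells, lymphocytes, mast cells and granulocytes, blood cells, adipocytes, atrial and conduction tissue, and nerve, mesothelium and valve were added for the cell types and tissues a piece of ventricle could hold. The genes named were Adrb3, Adrb1 and the 10 gene symbols with the largest change in each direction among those past the threshold with groups fully apart. Where fewer passed, the symbols with the smallest unadjusted p filled the 10. At most 2 other features per direction were added. From each list up to 4 members past the threshold were named, otherwise up to 2 with the smallest unadjusted p, and for lists of other cell types the most abundant marker. Some genes that these rules pick are not reported here.

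Depth is given by the signal over background of each array, and the number of rats limits the precision. The arrays lay on 5 slides scanned on 2 days. Slides 1, 3 and 4 and both days held both groups, so differences were also computed within them, placing each replicate hybridization with the array of its group closest to it. Slide and scan day were also fitted as blocks over all 13 arrays with the rat as a random block. Slide was further fitted as a random block without a term for the rat, leaving out the replicate hybridizations. In that fit the replicate labelings of 1 rat counted as separate replicates. Other alternatives were median scaling, quantile normalization, normexp background correction (offset 50) with either scaling, the authors' values, no filter and a stricter filter on dim probes, every probe, a trended and robust variance model, array weights, either labeling alone, the replicate hybridizations averaged in, all arrays with the rat as a block, position on the slide, the heart number as a block, and leaving out each rat. Alternatives added after seeing the data were leaving out WT hearts 2 and 6, the rats of the block on heart number without that block, and an exact permutation test of list means. For blocked fits, lists were tested with camera's preranked form on the fit's statistics, at the same preset correlation of 0.01. No estimated correlation was used there.

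The procedure was tested on simulated data for this comparison, with 15367 genes, 4 against 5 rats and 200 changed genes in each of 10 simulations. It recovered 60% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 97.8% of those changed by 2, with a mean of 8.4 false calls. These shares hold for 200 changed genes, which makes the Benjamini-Hochberg cutoff more lenient than in the data, where 1 gene passed. They do not give the power there: Lmnb1, lower by 0.78, had an adjusted p of 0.123 with limma. A list shifted by -0.25 was called in 10 of 10 simulations. With no change simulated, 0 genes passed with limma and a mean of 771 had an unadjusted p under 0.05, and 0 lists passed. Genes were simulated independently of each other, so these list results do not cover members that vary together. In the data the estimated correlation was 0.19 for MHC genes and 0.369 for matrix genes, and other splits of the rats gave a median of 6 lists.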

Results

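Transcripts of the left ventricle, the main pumping chamber of the heart, were compared between rats overexpressing Adrb3, a catecholamine receptor, and WT rats of the same age and sex. Of the 13 arrays, 6 came from 4 WT rats and 7 from 5 overexpressing rats. The 75th percentile of the processed signal ranged from 760.4 to 908.7 between arrays, and 55.2% to 67.8% of spots were well above background. The lowest shares were on WT heart 2 and on WT heart 6, at 55.2% and 58.7%. No array had a saturated spot (0 in total). All levels below are log2 signal minus the array's 75th percentile, with the SD between rats.

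Repeat arrays of a rat lay closer together than arrays of different rats. Over 14683 probes, the SD of the log2 difference was 0.174 and 0.186 for the 2 pairs of replicate labelings, and its median was 0.275 over 23 pairs of different rats of a group (0.231 to 0.309). Between groups the median was 0.300 over 30 pairs (0.234 to 0.328). The replicate hybridization WT heart 5 was closest to WT heart 4, at an SD of 0.147 against 0.235 for the next array of its group. Overexpressing heart 4 was closest to heart 3, at 0.190 against 0.243 for the next of its group and 0.225 for WT heart 1, the closest array of the other group.

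**Figure D1:**
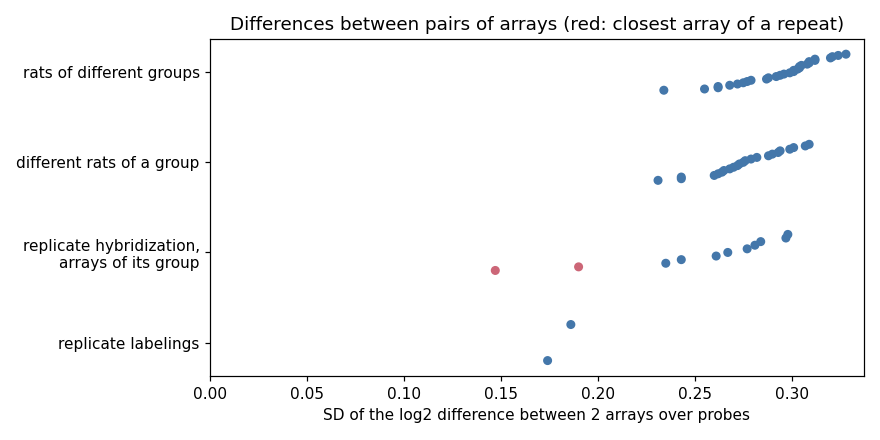
Each point is a pair of arrays, placed by the SD of their log2 difference over probes, with kinds of pair in separate rows and the closest array of each replicate hybridization in red. The replicate labelings (0.174 and 0.186) and the red points (0.147 and 0.190) lie below all pairs of different rats without a replicate hybridization, which start at 0.231.

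The probe for rat Adrb3, the gene the rats are labelled as overexpressing, was well above background on 0 of 6 WT arrays and on 1 of 7 overexpressing arrays, heart 6. Its level was -6.44 ± 0.445 (SD, n = 4) in WT and -5.96 ± 1.22 (SD, n = 5) in overexpressing rats. Heart 6 measured -4.10, and the other overexpressing arrays lay between -7.15 and -5.42. The difference of 0.477 did not exceed the spread between rats (exact two-sided permutation test, p = 0.532, where the smallest p the design allows is 0.00794). Without overexpressing rat 6 the difference was 0.0111 (exact permutation p = 0.971). No fold is given, since most arrays of both groups were not well above background. The labels do not state which sequence was introduced, so this probe need not read the transgene and does not check the labels. Adrb1, a related receptor gene well above background on 5 of 6 WT and 7 of 7 overexpressing arrays, was 0.14 lower in overexpressing rats (limma, Benjamini-Hochberg adjusted p = 0.751).

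Ak1, which encodes the cytosolic adenylate kinase that interconverts adenine nucleotides, rose 1.47-fold in overexpressing rats and was the 1 gene of 15367 to pass the threshold. Its level was 6.02 ± 0.0383 (SD, n = 4) in WT and 6.58 ± 0.0523 (SD, n = 5) in overexpressing rats, and all 5 overexpressing rats lay above all 4 WT rats. The difference was 0.55 ± 0.0463 (SE; limma, Benjamini-Hochberg adjusted p = 0.011), and the exact two-sided permutation p was 0.00794, the smallest this design allows. Within slides 1, 3 and 4, Ak1 was higher by 0.43, 0.63 and 0.56, and within the 2 scan days by 0.57 and 0.54. These values are not independent. Slides 3 and 4 and both scan days share WT rat 4, and both days share overexpressing rats 1 and 3. With slide as a block the difference was 0.52 and the adjusted p 0.0502, with scan day 0.55 and 0.000266, and without a filter on dim probes the adjusted p was 0.0741. Leaving out WT rat 3, 4 or 6 or overexpressing rat 6 or 7 gave adjusted p values of 0.0818, 0.0915, 0.0828, 0.0567 and 0.0657, with differences of 0.54 to 0.56.

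No gene was lower past the threshold (0 with limma), and the next smallest adjusted p was 0.123. The feature A_64_P048939 was lower past it with normexp and quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0348), normexp and the 75th percentile (0.0465), the authors' values (0.0497) and a trended, robust variance model (0.0343). The last called 8 genes, all but Ak1 lower. At an unadjusted p under 0.05, 484 genes were higher and 967 lower in overexpressing rats, 1451 in all against 768 by chance. The share of higher genes among them was 33.4%. It was 62.6% with median scaling, 54.9% with quantile normalization, 54.8% with normexp and quantile normalization, and 26.1% with normexp and the 75th percentile. In 541 genes, 3.52% of those tested, the groups did not overlap, against 1.59% by chance.

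Among gene symbols with the next smallest p in the upward direction, none past the threshold, Abcd2, a peroxisomal transporter of very long chain fatty acids, was 2.35-fold higher in overexpressing rats (limma, Benjamini-Hochberg adjusted p = 0.123). It was well above background on 2 of 6 WT and 7 of 7 overexpressing arrays, so its WT level and the fold are poorly measured. Lcn2, the siderophore-binding protein lipocalin-2, was 0.75 higher (1.68-fold, adjusted p = 0.123). Synm, the intermediate filament protein synemin, and the muscarinic receptor gene Chrm3 were higher by 0.56 and 0.55, and the endolysosomal channel gene Tpcn1 by 0.54. Cbr3, a carbonyl reductase, was higher by 0.45, the basement membrane collagen gene Col4a2 by 0.36, and Dus3l and the tubulin gene Tubb2a by 0.23 each. A second probe of Tpcn1 measured a difference of -0.00988. Among features without a symbol, LOC690323 was 0.80 higher. LOC500475 (C5h9orf43 in RefSeq) was 2.28-fold higher (adjusted p = 0.207), with a WT level that is likewise poorly measured. Of the 6 WT and 7 overexpressing arrays, LOC500475 was well above background on 1, a replicate hybridization outside the comparison, and 6, and Chrm3 and LOC690323 on 5 and 7 each.

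In the downward direction, also none past the threshold, Lmnb1, which encodes the nuclear lamina protein lamin B1, was 0.78 lower in overexpressing rats (1.71-fold; limma, Benjamini-Hochberg adjusted p = 0.123). Snhg11, a long non-coding RNA, was 0.56 lower, and the chemokine gene Ccl4 was 0.54 lower. Fam35a (Shld2 in RefSeq), a subunit of the shieldin complex of DNA repair, was 0.53 lower, though its second probe measured -0.0976. E2f8, a transcriptional repressor of cell cycle genes, was 0.49 lower. Noxa1, an activator of NADPH oxidase, was 0.39 lower, and the C-type lectin gene Cd209c 0.38 lower. The atypical chemokine receptor gene Ackr4 was 0.37 lower and the MHC gene RT1-M6-1 was 0.30 lower. Peo1 (Twnk in RefSeq), the mitochondrial DNA helicase, was 0.36 lower, while its second probe measured 0.0151. The features A_64_P048939 and AY325247, which have no symbol, were lower by 0.61 and 0.54.

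Genes of antigen presentation and of the interferon response fell in overexpressing rats, as did markers of lymphocytes and of mast cells and granulocytes, by camera at a preset correlation, with which 9 of the 30 lists passed, 5 upward and 4 downward. With an estimated correlation none passed (0 lists by camera, smallest adjusted p = 0.559), nor with fry (0 lists, smallest adjusted p = 0.137), where 3 lists had an unadjusted p under 0.05. The adjusted p values given below for lists with slide as a block also rest on the preset correlation.

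All 32 tested genes of the MHC list were lower in overexpressing rats, among them genes of molecules that present peptides to T cells. The list fell by 0.27 (camera, Benjamini-Hochberg adjusted p = 7.86e-09, or 0.559 with an estimated correlation). Under quantile normalization 31 were lower and 1 higher. The list mean was 0.60 ± 0.0695 (SD, n = 4) in WT and 0.33 ± 0.133 (SD, n = 5) in overexpressing rats, where rat 5, at 0.57, lay within the WT range of 0.51 to 0.68. RT1-CE13 was 0.38 lower (1.30-fold) and RT1-CE10 0.29 lower (1.22-fold). No member passed over all genes (0 with limma, 9 at an unadjusted p under 0.05), and 6 passed adjusted over the list alone. Within slides 1, 3 and 4 the list differed by -0.36, -0.26 and -0.15, within the scan days by -0.25 and -0.25, and with slide as a block by -0.25 (adjusted p = 1.29e-08). The values of slides 3 and 4 and of both scan days share WT rat 4, in every list. Both scan days also share overexpressing rats 1 and 3, so their values are not independent.

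Of 32 interferon response genes, 28 were lower and 4 higher, and the list fell by 0.13 (camera adjusted p = 0.000205; adjusted p = 0.559 with an estimated correlation), or by 0.0918 with median scaling. Psmb9, an immunoproteasome subunit gene, was 0.31 lower and Bst2, which encodes the antiviral protein tetherin, was 0.26 lower, with no member past the threshold over all genes or adjusted over the list alone (0 with limma, 7 at an unadjusted p under 0.05). The list differed by -0.068, -0.18 and -0.13 within slides 1, 3 and 4, by -0.052 and -0.12 within the scan days, and by -0.12 with slide as a block (adjusted p = 0.000139).

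Of 21 lymphocyte markers, 17 were lower and 4 higher, and the list fell by 0.23 (camera adjusted p = 0.0164; adjusted p = 0.559 with an estimated correlation). With normexp and quantile normalization 13 were lower and 8 higher, with a mean of -0.105. Cd6, a T cell surface receptor gene, was 0.54 lower, though its second probe measured -0.0969. Gzma, the gene of a granzyme of cytotoxic lymphocytes, was 0.49 lower (well above background on 5 of 6 WT and 7 of 7 overexpressing arrays), and the most abundant marker, the B cell factor gene Pax5, differed by 0.00111 and changed sign with several settings. No member passed over all genes or adjusted over the list alone (0 with limma, 6 at an unadjusted p under 0.05). Within slides 1, 3 and 4 the list differed by -0.38, -0.069 and -0.21, within the scan days by -0.27 and -0.28, and with slide as a block by -0.22 (adjusted p = 0.00211). The call was lost without WT rat 3 (-0.14, adjusted p = 0.179) and without overexpressing rat 1 (-0.16, adjusted p = 0.131).

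Of 12 mast cell and granulocyte markers, 9 were lower and 3 higher, and the list fell by 0.27 (camera adjusted p = 0.0342; adjusted p = 0.559 with an estimated correlation). Its mean was -0.124 with normexp and quantile normalization, -0.158 with the authors' values and -0.179 with normexp and the 75th percentile. The mast cell protease gene Mcpt10, well above background on 6 of 6 WT and 6 of 7 overexpressing arrays, was 0.85 lower (1.80-fold) and passed adjusted over the list alone as the 1 such member, with none past over all genes (0 with limma, 2 at an unadjusted p under 0.05). S100a9, a calcium-binding protein gene of neutrophils, was 0.45 lower and Mcpt8, the most abundant marker, 0.42 lower. At both the rats of the 2 groups overlapped, with unadjusted p values of 0.0454 and 0.11 by limma. The list differed by -0.30, -0.49 and -0.22 within slides 1, 3 and 4, by -0.45 and -0.22 within the scan days, and by -0.31 with slide as a block (adjusted p = 0.00824). The call was lost with no filter or a strict filter on dim probes (adjusted p = 0.0551 and 0.102), with the replicate hybridizations averaged in (0.055), on the rats numbered 1, 3 and 6 with the heart number as a block (0.0546) or without it (0.0671), and without WT rat 1, 3 or 4 or overexpressing rat 1 (0.138, 0.0825, 0.0764 and 0.0813, at -0.26 to -0.23).

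**Figure D2:**
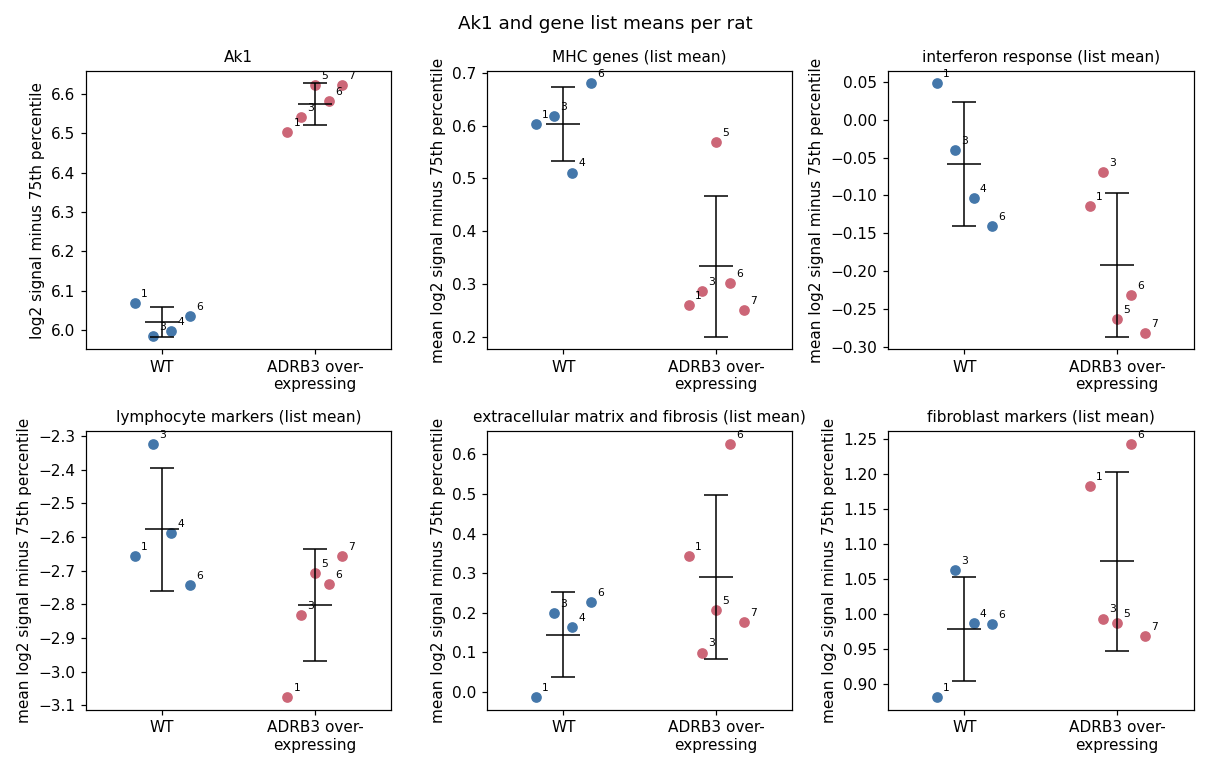
Each point is a rat, numbered by its heart, at its log2 signal minus the array's 75th percentile for Ak1 (WT 6.02, overexpressing 6.58) or at the mean of a gene list, with the mean and SD of each group as bars. For Ak1 the groups are fully apart, for MHC genes overexpressing rat 5 (0.57) lies among the WT rats (0.51 to 0.68), and for extracellular matrix genes overexpressing rat 6 (0.63) lies above the others.

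Genes of the extracellular matrix, fibroblast markers, cardiac stress markers, adipocyte markers and sarcomere genes rose as lists, each by 0.16 or less. Some of these lists name the same genes, so they are not independent. Col1a1 and Col3a1 stand in the matrix and fibroblast lists, and Des in the stress and sarcomere lists. Of 46 matrix and fibrosis genes 36 were higher and 10 lower, and the list rose by 0.15 (camera, Benjamini-Hochberg adjusted p = 0.000203; adjusted p = 0.559 with an estimated correlation). Besides Col4a2, the matricellular protein gene Thbs2 was 0.34 higher, with no member past over all genes or adjusted over the list alone (0 with limma, 4 at an unadjusted p under 0.05). Its mean differed by 0.23, 0.013 and 0.15 within slides 1, 3 and 4, by 0.043 and 0.18 within the scan days, and by 0.15 with slide as a block (adjusted p = 4.35e-05). Overexpressing rat 6 had the highest mean (0.63 against at most 0.34 in any other rat), and without it the difference was 0.062 (adjusted p = 0.0294). Without WT rat 1 it was 0.094 (adjusted p = 0.045), and on the rats numbered 1, 3 and 6 it was 0.218. Rat 6 was also the highest of the 9 rats for adipocyte markers, atrial and conduction markers, and nerve, mesothelial and valve markers, at 0.12, 0.69 and -1.43 against at most -0.28, 0.39 and -1.82 in the other rats. This was not particular to those lists, since rat 6 was the highest in 10 of all 30.

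Of 20 fibroblast markers 18 were higher and 2 lower, and the list rose by 0.096 (camera adjusted p = 0.00639; adjusted p = 0.559 with an estimated correlation). The elastic fibre gene Mfap4 was 0.18 higher and the platelet-derived growth factor receptor gene Pdgfra 0.11 higher, while Gsn, the most abundant, was 0.076 lower, with a changed sign among 3 alternatives. No member passed over all genes or adjusted over the list alone (0 with limma, 1 at an unadjusted p under 0.05). Between groups it differed by 0.26, -0.019 and 0.089 within slides 1, 3 and 4, by 0.060 and 0.13 within the scan days, and by 0.13 with slide as a block (adjusted p = 4.35e-05). Without overexpressing rat 6 the difference was 0.054 (adjusted p = 0.0445), and the call was lost without WT rat 1 (0.063, adjusted p = 0.0569) and without overexpressing rat 1 (0.069, adjusted p = 0.0813). On the rats numbered 1, 3 and 6 the mean was 0.164.

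Of 30 cardiac stress and hypertrophy markers 22 were higher and 8 lower, and the list rose by 0.073 (camera adjusted p = 0.0238; adjusted p = 0.559 with an estimated correlation). Flnc, which encodes the actin cross-linker filamin C, was 0.23 higher and Xirp1, a gene of the intercalated disc, 0.16 higher, with no member past over all genes or adjusted over the list alone (0 with limma, 2 at an unadjusted p under 0.05). The list differed by 0.16, -0.000955 and 0.12 within slides 1, 3 and 4, by 0.029 and 0.11 within the scan days, and by 0.10 with slide as a block (adjusted p = 0.00211). The call was lost without WT rat 4 (0.067, adjusted p = 0.0764), overexpressing rat 1 (0.053, adjusted p = 0.102) or overexpressing rat 6 (0.016, adjusted p = 0.103), and on the rats numbered 1, 3 and 6 without the heart number as a block (0.117, adjusted p = 0.0671). The mean was 0.113 without overexpressing rat 3, 0.108 without WT rat 6, 0.115 with median scaling and 0.048 without a filter on dim probes.

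Of 21 adipocyte markers 14 were higher and 7 lower, and the list rose by 0.16 (camera adjusted p = 0.0238; adjusted p = 0.559 with an estimated correlation). Dgat2, a triglyceride synthesis enzyme gene, was 0.35 higher and the lipase-family gene Pnpla3 0.53 higher (well above background on 5 of 6 WT and 7 of 7 overexpressing arrays), while Cidea, the most abundant, was 0.17 lower, with no member past over all genes or adjusted over the list alone (0 with limma, 2 at an unadjusted p under 0.05). The list differed by 0.12, -0.23 and 0.28 within slides 1, 3 and 4, by 0.00911 and 0.24 within the scan days, and by 0.13 with slide as a block (adjusted p = 0.073). The call was lost with a strict filter on dim probes (0.044, adjusted p = 0.108) and without WT rat 1 (0.081, adjusted p = 0.131), WT rat 4 (0.15, 0.0764), overexpressing rat 1 (0.16, 0.0626) or overexpressing rat 6 (0.041, 0.129). The mean was 0.0886 with normexp and the 75th percentile, 0.226 without WT rat 6, 0.254 without overexpressing rat 7 and 0.268 on the rats numbered 1, 3 and 6.

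Of 31 genes of the sarcomere and cardiomyocyte structure 19 were higher and 12 lower (26 higher with median scaling), and the list rose by 0.031 (camera adjusted p = 0.0352; adjusted p = 0.601 with an estimated correlation). Mybpc3, which encodes cardiac myosin-binding protein C, was 0.18 higher and Tmod1, the actin-capping protein tropomodulin, 0.24 higher, with no member past over all genes or adjusted over the list alone (0 with limma, 4 at an unadjusted p under 0.05). The shift was 0.016, 0.055 and -0.000823 within slides 1, 3 and 4, -0.00732 and 0.047 within the scan days, and 0.011 with slide as a block (adjusted p = 0.208). The call was lost without WT rat 3 (-0.00993, adjusted p = 0.745), overexpressing rat 1 (0.030, 0.0816) or overexpressing rat 7 (0.016, 0.108), with array weights (0.0513), with the second labeling alone (0.0763), and on the rats numbered 1, 3 and 6 (0.0236) with the heart number as a block (0.156) or without it (0.132). The mean was 0.0723 with median scaling, 0.0538 with quantile normalization, 0.0535 with position row as a block and 0.053 without WT rat 6.

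The lists of metabolism did not pass with camera. Fatty acid oxidation and lipid handling had 30 of 50 genes higher (mean 0.041, adjusted p = 0.0517), with Dgat2 and the lipid droplet gene Plin5 (0.21 higher) leading, and with median scaling 42 were higher (mean 0.0825). The mitochondrial respiratory chain list had 42 of 58 genes lower (mean -0.037, adjusted p = 0.0906), though its mean was 0.00426 with median scaling. The complex I subunit gene Ndufa8 was 0.29 lower and the 1 member to pass adjusted over the list alone, and Ndufs6 was 0.098 lower. Glucose metabolism had 19 of 40 genes higher (mean 0.00643, median -0.00304, camera upward, adjusted p = 0.626), with the glycolytic gene Eno1 0.36 higher and Ldhb 0.11 lower. With median scaling 31 were higher (mean 0.048), and with normexp and quantile normalization 27. Redox and antioxidant genes were split, 20 higher and 21 lower (mean 0.016, median -0.00031, camera upward, adjusted p = 0.475), with Txn2 0.19 higher and Rac2 0.27 lower. With median scaling 31 were higher and 10 lower (mean 0.0571).

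Inflammatory cytokines and chemokines had 27 of 36 genes lower (mean -0.12, camera adjusted p = 0.0917), and fry's test for change in either direction gave an adjusted p of 0.00334, the 1 list to pass that test. Of its members 3 passed adjusted over the list alone: Lcn2, higher, and the chemokine genes Ccl4 and Ccl5, lower, the last by 0.68 and named after its values were seen. Lcn2 was also the 1 such member of the renin-angiotensin and corticosteroid list, where 14 of 20 genes were higher (mean 0.088, camera adjusted p = 0.0917) and Enpep was 0.20 lower. Of 35 immediate early genes 21 were higher (mean 0.068, adjusted p = 0.0607), with Jund 0.23 and Dusp1 0.37 higher. Macrophage and myeloid markers had 20 of 28 genes lower (mean -0.086, adjusted p = 0.104), with the chemokine receptor gene Cx3cr1 0.32 lower, Fcgr3a 0.65 lower (well above background on 5 of 6 WT and 5 of 7 overexpressing arrays) and the abundant Lyz2 0.12 lower. Endothelial markers had 22 of 29 genes lower (mean -0.064, adjusted p = 0.104), where Gpihbp1 was 0.45 higher, Sox7 0.27 lower and the abundant Kdr 0.034 lower, though 0.00752 higher with median scaling. Smooth muscle and pericyte markers had 13 of 17 genes higher (mean 0.068, adjusted p = 0.0917), with Ano1 0.28 higher, Abcc9 0.23 lower and Des 0.063 higher.

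Ion channels of the cardiac action potential had 20 of 32 genes higher (mean 0.060, camera adjusted p = 0.104), with the potassium channel gene Kcna5 0.76 higher (well above background on 3 of 6 WT and 7 of 7 overexpressing arrays). Circadian clock genes had 16 of 23 higher (mean 0.056, adjusted p = 0.165), with Csnk1e 0.14 and Tef 0.15 higher, though other probes of Csnk1e measured -0.0118 and 0.000478. With normexp and the 75th percentile 11 of the clock genes were higher and 12 lower (mean 0.0187). Atrial and conduction markers had 10 of 16 higher (mean 0.12, adjusted p = 0.29), with Tbx3 0.32 lower and the abundant Myl4 0.014 higher. Angiogenesis and endothelial activation had 23 of 41 higher (mean 0.037, adjusted p = 0.339), with Apln 0.16 and Klf2 0.29 higher. Nerve, mesothelial and valve markers had 16 of 23 higher (mean -0.032, median 0.12, camera upward, adjusted p = 0.475), with Wif1 0.24, Sox9 0.40 and Fmod 0.39 higher. For Fmod, overexpressing rat 6 measured 2.38 against at most 1.31 in any other rat (limma, unadjusted p = 0.34). Heat shock and chaperone genes had 18 of 42 higher (mean 0.00388, median -0.00314, camera upward, adjusted p = 0.808), with Hspa2 0.40 higher and Atf4 0.11 lower, and with median scaling 28 were higher (mean 0.0454).

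The lists of receptor signalling gave the largest camera p values together with calcium handling, blood cells and cell cycle. Adrenergic receptors and cAMP signalling had 22 of 38 genes lower (mean -0.034, adjusted p = 0.871), with the adenylate cyclase gene Adcy9 0.22 lower and the protein kinase A subunit gene Prkar2b 0.42 higher. Nitric oxide and cGMP signalling had 16 of 31 lower (mean -0.015, median -0.00334, camera upward, adjusted p = 0.871), with Arg1 0.38 lower and Npr2 0.15 higher. Calcium handling had 19 of 33 lower (mean -3.11e-06, median -0.016, camera upward, adjusted p = 0.871), with Calm3 0.22 and Calr 0.44 lower. Blood cell markers had 8 of 13 higher (mean -0.12, median 0.032, camera upward, adjusted p = 0.871), with the hemoglobin-stabilizing protein gene Ahsp 1.26 lower, Klf1 0.32 higher and Hba1 0.032 higher. Cell cycle genes had 15 of 26 lower (mean -0.011, median -0.011, camera upward, adjusted p = 0.916), with Mcm7 0.15 higher and Tyms 0.25 lower. Of the 6 WT and 7 overexpressing arrays, Klf1 was well above background on 4 and 3, and Tyms on 4 and 5. The means of the adrenergic, nitric oxide, calcium, cell cycle and valve lists were positive with median scaling, at 0.00757, 0.027, 0.042, 0.030 and 0.00977.

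Without overexpressing rat 3, the number of genes past the threshold was 13, of which 2, Ak1 and Abcd2, were higher and 11 lower in the other 4 overexpressing rats (limma, Benjamini-Hochberg). Named here after their values were seen, the lower symbols were Tnfrsf13c, Plekho2 (-5.05), Pcdhga4 (-2.40), Susd3 (-1.91), Prima1 (-1.77) and Cnksr1 (-1.49), beside 5 features without a symbol. Tnfrsf13c was well above background on 0 of the 5 arrays of these 4 rats and lay at least 49-fold lower there than in WT (adjusted p = 3.54e-05). For this fold, each of these arrays was counted at its lowest well-measured signal or the probe's own value, whichever was higher. Among the features without a symbol, A_64_P087842 was also well above background on 0 of the 5 arrays (at least 16.3-fold lower), and A_44_P290734 and A_64_P045053 on 1 of 5 each. At 10 of the 11 probes, rat 3 and its closest array, the replicate hybridization heart 4, lay near the WT rats, within 0.25 of the way from the WT mean to the dim rats. At A_64_P307087 rat 3 (-3.72) and heart 4 (-3.80) lay between WT (-3.51) and the dim rats (-4.09). WT rat 3 was the lowest WT rat at all 11.

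**Figure D3:**
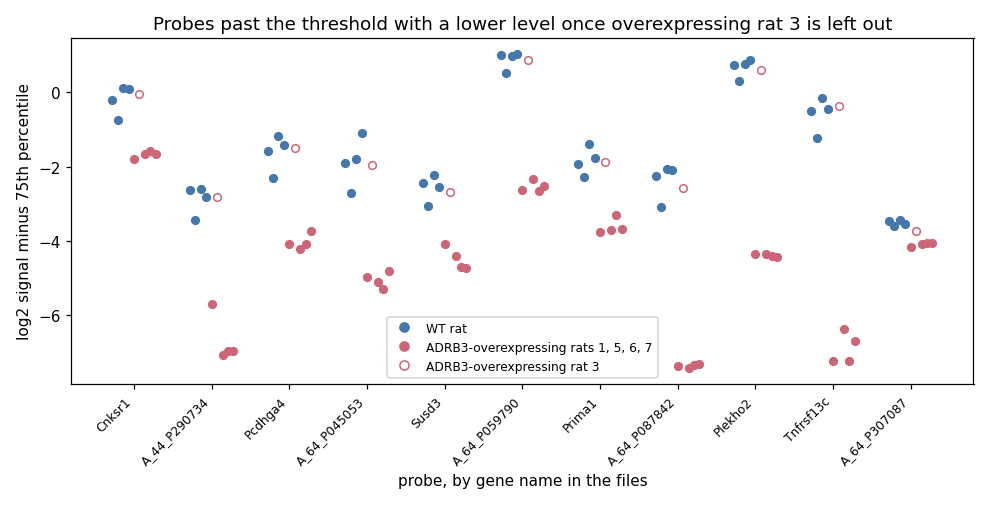
Each point is a rat at its log2 signal minus the array's 75th percentile, for the 11 probes lower past the threshold once overexpressing rat 3 is left out, with WT rats in blue, overexpressing rats 1, 5, 6 and 7 in filled red and rat 3 as open circles. Rat 3 lies near the WT rats at 10 of the 11 probes, while the other overexpressing rats lie lower, at least 49-fold for Tnfrsf13c, which is not well above background in them.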

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

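The ratio that picks single rats here was set before the data were examined, while the tests of slide and scan day, of look-alike probes, of class I against class II genes and of overexpressing rat 6 were chosen after the results were seen. For each named gene, gene list and array measure, the gap between the highest or lowest rat and its nearest neighbour in the group was divided by the group's range and set against Dixon's 95% limit. Of 246 such sets of values 17 passed it, and chance alone passes about 1 in 20.

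Among WT rats, rat 1 stood apart from the other 3 for Tubb2a (2.25 against 2.21 in the others) and the ion channel list (0.367 against 0.437 to 0.451). WT rat 4 stood apart for the complex I gene Ndufa8 (3.39 against 3.50 to 3.52) and for immediate early genes (-0.658 against -0.942 to -0.926). WT rat 6 stood apart for Ndufs6 (6.32 against 6.26 to 6.27), the endothelial receptor gene Kdr (3.65 against 3.94 to 3.96), Pnpla3 (-3.48 against -4.50 to -4.49), the stress response factor gene Atf4 (3.27 against 3.16 to 3.18) and the renin-angiotensin and corticosteroid list (-0.469 against -0.705 to -0.680).

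Among overexpressing rats, rat 1 was the lowest for Ccl4 (-4.00 against -3.90 to -3.87), and rat 3 was the highest for Bst2 (3.30 against 3.03 to 3.10) and the adrenergic list (-0.800 against -0.839 to -0.828). Rat 5 was the highest for RT1-CE13 (0.406 against 0.039 to 0.139), for the whole MHC list (0.569 against 0.251 to 0.301) and for the hemoglobin gene Hba1 (8.28 against at most 8.06). Rat 6 was the highest for Ano1 (-0.963 against -1.12 to -1.09) and for inflammatory cytokines and chemokines (-1.75 against -2.04 to -1.99).

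MHC genes were lower in 4 of 5 overexpressing rats, with rat 5 among the WT rats. Scan day and slide as the whole cause are argued against: the difference was -0.253 with scan day in the model (exact permutation within days, p = 0.0167), and -0.254 ± 0.0772 (SE) with slide as a block, a fit that moved other genes. The list stayed past the threshold in that fit by camera at the preset correlation. In the main fit it did not pass with an estimated correlation (camera adjusted p = 0.559). Too few splits within slides exist for an exact test (6). The fall was not confined to RT1 probes: 7 antigen presentation genes outside the RT1 family (B2m, Cd74, Tap1, Tap2, Psmb8, Psmb9 and Psmb10) were all lower, by -0.184 on average (exact two-sided permutation p = 0.0159). Whether look-alike RT1 probes read a single signal stays open, since genes outside the family cannot show it. B2m and Cd74 also belong to the MHC list itself, and Tap1, Tap2, Psmb8, Psmb9 and Psmb10 to the interferon list. Whether the tissue held fewer leukocytes stays open: class I genes differed by -0.276 (exact p = 0.0159) and class II genes, which leukocytes express, by -0.251 (exact p = 0.214), and the gap of -0.025 between them (exact p = 0.913) decides neither way, while the leukocyte lists lay lower too, lymphocyte markers by -0.225 and mast cell and granulocyte markers by -0.27 (camera adjusted p = 0.559 for each with an estimated correlation), and macrophage markers by -0.0855 (0.727). Overexpression itself and a different MHC haplotype in some rats also stay open and were not tested, and Tap1, Tap2, Psmb8 and Psmb9 lie in the MHC region themselves.

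Matrix and fibroblast genes were higher as lists, with overexpressing rat 6 the highest rat in both. Without rat 6 the matrix difference was 0.062 in place of 0.146 (exact two-sided permutation p = 0.457 and 0.27), so a large part of the shift may rest on this rat. Tissue from outside the ventricle wall in the piece of rat 6 is a candidate source, though not a specific one: this rat was the highest of the 9 in 3 of 3 lists of other tissue (atrial and conduction, nerve, mesothelium and valve, and adipocytes), but also in 5 of 25 further lists, among them cardiac stress, smooth muscle and angiogenesis. Some members of these lists, such as Fmod, also belong to the matrix list, and ventricle expresses others, such as the abundant Cidea, so the lists are not independent. Fibrosis with overexpression in the remaining rats was not excluded and stays open.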

How the results depend on the processing

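The Adrb3 result (17 alternatives) and the precision of repeat arrays (2 alternatives) kept direction and side of the threshold throughout; leaving out WT hearts 2 and 6, the 3-rat comparison without its block and the permutation of list means were chosen after seeing the data. Unless stated, the cause was not tested. In place of 1 gene, limma with Benjamini-Hochberg adjustment called 2 with normexp under either scaling, with the authors' values, with all arrays and the rat as a block, and with scan day as a block, and 8 with a trended, robust variance model; Ak1 was among them each time, at adjusted p values of 6.41e-05 to 0.00441. It called 0 with slide as a block (842 at an unadjusted p under 0.05), 0 without WT hearts 2 and 6 (1238), and 0 to 13 when each rat was left out. Without a filter the 1 gene was Lipi, not Ak1.

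With the heart number as a replicate block, on the rats numbered 1, 3 and 6 in both groups, 0 genes passed (1433 at an unadjusted p under 0.05), and on the same 6 rats without the block also 0 (1311), where fewer rats were tested. Ak1 differed by 0.513 in both, with adjusted p values of 0.446 and 0.366. Deviations of same-numbered rats correlated at 0.106, 0.0347 and 0.124 across genes, so the numbers were not read as pairs. Gsn differed by 0.0869, Pax5 by -0.147 and Myl4 by -0.0554 in both.

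In place of 9 lists, camera called 16 without a filter on dim probes, 14 with scan day as a block, and 3 to 12 when each rat was left out, 3 without overexpressing rat 1. It called 0 with an estimated correlation, fry called 0, and the exact permutation of list means called 0, with 3 lists at an unadjusted p under 0.05. That permutation could hardly call a list: the smallest p it allows is 0.00794 before adjustment over 30 lists, so 1 list alone could not pass. MHC, interferon and matrix lists kept their calls under every other alternative tried.

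Values near 0 changed sign. Pax5 measured -0.0117 with normexp and the 75th percentile, -0.0343 with the authors' values, -0.0146 with array weights, -0.0194 with the second labeling, -0.0347 with slide as a random block, -0.0421 without WT hearts 2 and 6, and -0.146 to 0.148 without single rats. Kdr measured 0.00752 with median scaling and 0.00399 with slide as a block. Myl4 measured -0.0166 with slide as a random block and -0.0114 to 0.0404 without single rats, Gsn -0.177 to 0.0412, and Hba1 -0.0224 to 0.0647 (-0.022 without WT hearts 2 and 6). Within slide 3, of 1 rat per group, the cardiac stress, fibroblast and adipocyte lists differed by -0.000955, -0.0191 and -0.225, and the sarcomere list by -0.000823 within slide 4 and -0.00732 within scan day 1. Dim probes limit the least abundant genes: 15367 of 26115 gene names were bright enough to be tested.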

Other observations

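The tests of this part on features without a symbol, on neighbouring genes, on failed hybridization, on shared probe sequence and on rat 3's label, by Ak1 and by its position among the groups, were chosen after the results were seen. The splits of the rats were not. Features without a gene symbol, such as probes known only by an identifier or an accession, made up 27.3% of the features tested, 49.1% of those lower at an unadjusted p under 0.05 and 15.1% of those higher. Of these features 67.4% were lower in overexpressing rats, against 48.0% of symbols. Compared within 10 bins of intensity, features without a symbol lay 0.0671 further down (-0.0671) in overexpressing rats than symbols did (exact two-sided permutation p = 0.00794, the smallest the design allows).

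Ak1 and Lcn2 lie 7 tested genes apart on chromosome 3 in the gene order of the RefSeq table. Among 10000 random draws of 10 genes, 4.98% held a pair as close. The 19 tested genes around Ak1, other than Lcn2, differed by -0.171 to 0.184 with a median of 0.067, and 2 of them had an unadjusted p under 0.05.

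At 11 probes, among them those of Tnfrsf13c and Plekho2, overexpressing rats 1, 5, 6 and 7 lay below rat 3 and the WT rats, by 0.576 to 5.05 on the log2 scale against WT at the 7 probes well above background on all arrays of these rats. Failed hybridization of single arrays is argued against: with each of the 4 left out in turn of the choice of probes (7 to 11), its median position between the WT mean (0) and the other dim rats (1) was at least 0.989, at 30 of 35 choices it lay nearer the dim rats, and rat 3 lay at a median of at most 0.019. Whether many of these probes read 1 transcript through a short shared sequence stays open. Of these, 6 of the 11 probes share a word of 7 bases, against a median of 2 and at most 4 in 2000 random sets of probes (permutation p over these sets = 5e-04, the smallest they can give). The word length was chosen after reading the sequences, which this p does not account for, and 61 tested probes hold that word. A wrong label of rat 3 stays open. At Ak1, which passed without this rat (limma, Benjamini-Hochberg adjusted p = 0.0075), rat 3 measured 6.541. That lay within the other overexpressing rats (6.504 to 6.624) and 12.3 SD of the WT rats above the highest of them (6.068). Ak1 goes with the label as given, but it is 1 gene, and its values were known when the check was chosen. At 10 of the 11 dim probes rat 3 lay near the WT rats instead. The position of rat 3 over many genes, 0.618 between the WT mean (0) and the overexpressing mean (1), decides neither way, with rats 1 and 7 at 0.626 and 0.634 and WT rat 4 at 0.611. Overexpression or an inherited difference between rats was not tested; of 60 genes with a gap of over 2 between rats, 27 split off more than 1 rat and 21 of these split the rats another way.

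Of 100 splits of the 9 rats into 4 and 5, drawn from 126 with the real one included, 12 gave at least the 1 gene called, and the highest other split gave 11, so chance cannot be excluded for that count. The split with 11 genes set overexpressing rats 1, 5, 6 and 7 against the rest. That is the division already seen at the dim probes, so this split adds no separate support for it. For genes at an unadjusted p under 0.05, 2 splits, the real one included, gave at least the real 1451, the highest other giving 1488. That other split was the real grouping with 1 overexpressing rat placed among the WT rats. So large a count was rare among the splits, but these ignore slide and cannot separate group from slide. The count was 842 with slide as a fixed block and 1835 with slide as a random block, against 768 expected by chance. The random-block fit had no term for the rat and took the replicate labelings of 1 rat as separate replicates, which can inflate its count. For lists called by camera, 26 splits gave at least the real 9, the highest other giving 15, so chance cannot be excluded.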
